A study of Gossypium hirsutum with 45 samples.

How the data were processed

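RNA sequencing was done on leaves, roots and stems of upland cotton (Gossypium hirsutum) seedlings at the 3-leaf stage. The plants were of the line Hengmian HD008 and stood in 10% PEG 6000, a polymer that lowers the water potential of the solution without entering the cells and is used to imitate drought. Per the labels, each of the 3 tissues was sampled before treatment (0 min) and after 10, 30, 60 and 180 min, with 3 libraries in each of the 15 groups and 45 in all. Nothing in the labels says whether replicates were separate plants or pools, so p-values measure only the spread between these libraries, which may be partly technical. No untreated plants sampled at the later times are among the libraries used here.

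The deposited table gives FPKM (fragments per kilobase of gene, scaled for the depth of the library) for 75376 genes, with their coordinates and a description for 58053 of them. Of the descriptions, 11103 carried a Swiss-Prot name and 46950 only Pfam domains, and 17323 genes had none. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. The genome build is not given in the sources used here. Coordinates are those of the deposited table, where gene names of the form Gohir.A11G111300 hold the subgenome and chromosome (A11), and 474 genes lie on scaffolds. The supplied RefSeq gene table matched 0 of the gene identifiers and was not used. How reads that fit both the A and the D copy of a gene were counted, and whether counting used strand, is not given in the sources used here, so values of near-identical copies and of overlapping genes are uncertain.

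The unit was checked on the values. Multiplying the deposited FPKM by gene length gave whole reads for 100% of values within 0.01 read (largest deviation 0.00183). The library denominators behind the deposited FPKM were not the library totals. They equalled median-of-ratios size factors over the 42188 genes above 0 in all libraries, times the geometric mean of the totals, with a largest relative difference of 1.71e-08. The totals read back this way were 16373617 to 21774520 reads per library. One read in a gene of 1 kb was worth 0.0440 to 0.0899 FPKM. Gene lengths were a multiple of 3 in 47.0% of genes, so they hold untranslated parts. Of the table's value columns, 0 could not be mapped to a group. The 2 columns that share 1 name belong to root at 0 min and are called libraries x and y here, with no replicate number.

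Values were tested as log2(FPKM + 1), so a log2 change understates the change of genes with low FPKM. Genes with FPKM of at least 1 in at least 3 libraries of a fit were kept. For each tissue limma 3.58.1 in R 4.3.3 was fitted to the 15 libraries with 1 factor of 5 times (empirical Bayes with a trend and robust settings), each time was contrasted with 0 min, and a combined F test covered the 4 contrasts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Differences between tissues at 0 min, and differences of the response between tissues (interaction), came from 1 fit of all 45 libraries. All adjusted p-values of single genes are from limma.

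33 gene lists were fixed from words in the descriptions before the data were examined, so they hold some genes of other functions. They cover phosphoinositide and lipid signalling, calcium, hormones, stress proteins, transcription factors, growth, metabolism and markers of tissues. Lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over lists and times within a tissue. With the correlation estimated from the data instead, 0 of the 86 camera calls passed, and each list call in the text is given with that second p. The self-contained test fry was run as well. Genes named in the text follow a rule fixed before the data were examined: at each time the 2 described genes with the largest rise and the 2 with the largest fall whose 3 treated libraries all lay beyond the 3 libraries at 0 min, and for each list with a camera call in the tissue, and always for 6 lists of phosphoinositide and abscisic acid genes, the 2 members with the smallest F test p. For differences between tissues these are the 3 described genes with the smallest interaction p, and at 0 min the 3 with the largest difference each way. The text names a subset, and says where another gene was chosen after its values were seen.

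The procedure was tested on simulated data for 180 against 0 min, with sets of 66 or 67 genes changed. In leaf (46265 genes) 0% of genes set to a log2 change of 0.5 were recovered, 32.8% at 1 and 78.8% at 2. In root (46711 genes) they were 0%, 43.3% and 86.4%, and in stem (47698 genes) 1.49%, 32.8% and 74.2%. Unchanged genes called were 3, 4 and 3. Far more genes were called in the real data, where these rates may not apply.

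Alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio and quantile scaling, the replicate number as a block, precision weights, library weights, a log2 change of at least 1, fits of the 6 libraries compared or of all 45, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, division of each library by its own total, the block with root libraries x and y in the other order, and for the lists the removal of single libraries. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (version 1.17.8) and drawn with matplotlib 3.10.9. No negative binomial model of counts was used, since the deposited unit is FPKM.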

Results

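Transcript levels of 75376 genes were measured in 45 libraries of cotton seedlings, from leaf, root and stem at 0, 10, 30, 60 and 180 min in 10% PEG 6000, with 3 libraries per group. Libraries held 16373617 to 21774520 reads counted in genes. The series asks how early drought stress acts on gene expression, with the phosphatidylinositol signalling system as its theme: kinases that phosphorylate phosphatidylinositol, phospholipase C that cleaves the product into diacylglycerol and inositol phosphate, and the enzymes that turn over both. Parentheses after a gene give its chromosome, start and end. Levels are means ± SD of 3 libraries in FPKM, and medians of gene lists are of log2 changes. All times after 0 min are compared with plants sampled before treatment, so hours of the day and handling ran along with the PEG.

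At 0 min the tissues differed in genes that mark them. The small subunit of Rubisco, which fixes carbon dioxide in green tissue, stood far higher in leaf than in root, as in Gohir.A07G173466 (A07, 79459862 to 79460867), at 6748 ± 537 FPKM in leaf and 1.09 ± 1.83 in root (log2 difference 11.99, adjusted p = 5.09e-24). Root led in a metallothionein, a metal-binding protein, Gohir.D13G229100 (D13, 64205949 to 64207757), at 1.1 ± 0.334 FPKM in leaf and 3111 ± 752 in root (log2 difference -10.52, adjusted p = 2.41e-21), and in the dirigent-like gene Gohir.D05G380000 (D05, 65284134 to 65284884), at 0.023 ± 0.0398 FPKM in leaf and 996 ± 286 in root (log2 difference -9.89, adjusted p = 3.28e-25), of a family that steers lignan coupling. Between root and stem the largest differences included a protease inhibitor and lipid transfer family gene, Gohir.D10G116300, listed at 0 in root and at 1466 ± 596 FPKM in stem. A leaf lipoxygenase, of the family that starts jasmonate synthesis, was Gohir.D05G070100 (D05, 5572546 to 5583022), at 168 ± 89.2 FPKM in leaf and 1.44 ± 1.57 in stem (log2 difference 6.17, adjusted p = 3.57e-13). Summed over the list of 440 photosynthesis genes, FPKM at 0 min were 36940 in leaf, 8263 in stem and 3314 in root, and over 200 mineral nutrient transporters 1037, 725 and 3133. With limma on the 54622 genes kept in the fit of all libraries, 25786 genes differed between leaf and root (12961 higher in leaf), 16748 between leaf and stem (9675 higher in leaf) and 22932 between root and stem (11521 higher in root). Without the libraries numbered 2 the last pair of counts fell to 9889 and 14032.

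In leaf at 10 min a pectate lyase, which cleaves wall pectin, fell: Gohir.D12G190100 (D12, 54115180 to 54117097) from 152 ± 70.6 to 7.94 ± 5.36 FPKM (log2 change -4.27, SE 0.59, adjusted p = 0.00735). A cotton fibre expressed protein, Gohir.A11G111300 (A11, 12120563 to 12121484), rose from 5.92 ± 2.15 to 142 ± 48.9 FPKM (log2 change 4.37, SE 0.44, adjusted p = 0.0013). Of 61 measured phosphatidylinositol kinases, 0 rose and 5 fell (0 and 8 adjusted over the list alone). The median was -0.34 (camera adjusted p = 2.01e-08, adjusted p = 0.787 with an estimated correlation). Of 28 genes of inositol synthesis and inositol phosphate kinases, 0 rose and 0 fell (2 and 0 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0132, adjusted p = 0.94 with an estimated correlation). Of 59 proline and soluble sugar genes, 6 rose and 1 fell (14 and 1 adjusted over the list alone). The median was 0.16 (camera adjusted p = 4.34e-05, adjusted p = 0.787 with an estimated correlation). Among 85 gibberellin and cytokinin genes 3 rose and 0 fell (8 and 1 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.00324, adjusted p = 0.461 with an estimated correlation). Lists that lost the call on leaving out single libraries were early auxin genes, where 6 rose and 0 fell of 148 (10 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.0133, 0.566 without 0 min replicate 3, adjusted p = 0.978 with an estimated correlation), AP2/ERF factors, where 3 rose and 1 fell of 59 (6 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.0444, 0.307 without 0 min replicate 1, adjusted p = 0.978 with an estimated correlation), and antioxidant enzymes, where 3 rose and 0 fell of 317 (2 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.0469, 0.575 without 10 min replicate 2, adjusted p = 0.978 with an estimated correlation). Inositol synthesis lost it too (adjusted p = 0.0676 and 0.167 without 10 min replicates 1 and 2).

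Growth lists in leaf at 10 min had camera calls with almost no called member. Of 870 ribosomal protein genes 0 rose and 0 fell (0 and 0 adjusted over the list alone). The median was 0.26 (camera adjusted p = 1.02e-12, adjusted p = 0.978 with an estimated correlation). Of 199 histone and cell cycle genes 0 rose and 1 fell (0 and 0 adjusted over the list alone). The median was 0.42 (camera adjusted p = 4.13e-05, adjusted p = 0.978 with an estimated correlation). Of 215 photosynthesis genes 1 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0281, adjusted p = 0.981 with an estimated correlation). These lists move along the main axis on which libraries of 1 leaf group differ from each other: 83.9% of the histone and cell cycle genes, 73.6% of the ribosomal and 79.1% of the photosynthesis genes load on its positive side, against 26.2% of phosphatidylinositol kinases and 28.8% of AP2/ERF factors. On that axis the 0 min leaf libraries lay at 55.9, 21.4 and -77.2. Histone genes lost their call on leaving out 1 library (adjusted p = 0.151 without 0 min replicate 3), and so did photosynthesis genes (adjusted p = 0.855 without 0 min replicate 3 and 0.202 and 0.515 without 10 min replicates 2 and 3). In total limma called 698 of 46265 genes at 10 min in leaf, 409 higher and 289 lower, or 398 and 388 with each library divided by its own total. Without 0 min replicate 1 there were 210 higher and 232 lower, and without 10 min replicate 1 153 and 160. The count was 159 and 340 without 0 min replicate 2 or 3, and 2 in a fit of the 6 libraries alone.

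**Figure D1:**
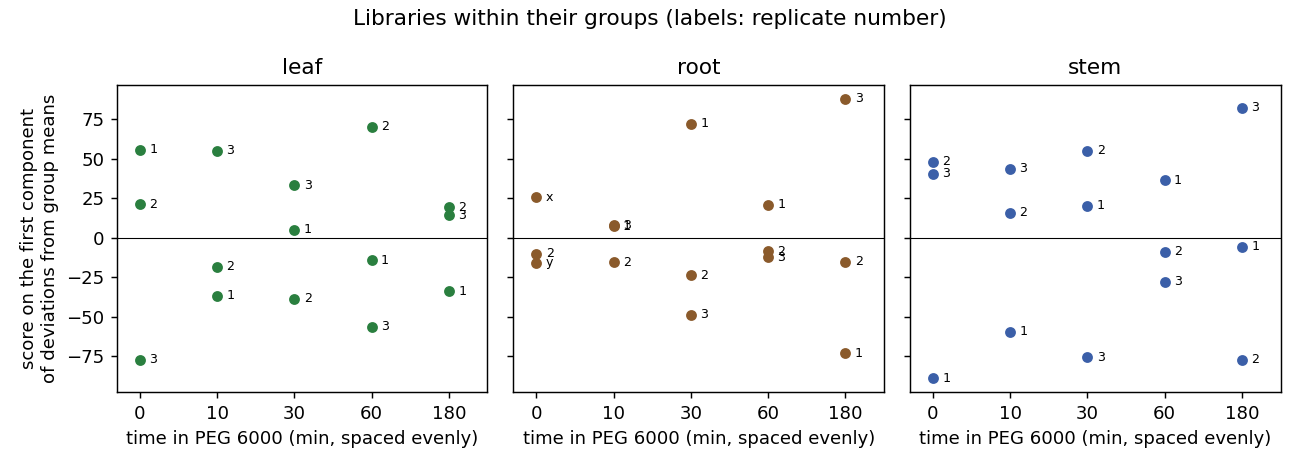
Position of each library (dots) on the main axis of differences within the groups of its tissue (vertical axis) by time in PEG 6000 in minutes, spaced evenly (horizontal axis). The axis holds 36.9% of the variance within groups in leaf, 36.6% in root and 45.03% in stem.

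At 30 min in leaf a phosphate-induced protein, Gohir.D11G117800 (D11, 11098906 to 11100308), rose from 3.49 ± 2.72 to 126 ± 7.43 FPKM (log2 change 4.98, SE 0.54, adjusted p = 0.000177) and an AP2 factor, Gohir.A12G071200 (A12, 22928196 to 22929352), from 3.27 ± 3.64 to 101 ± 84 FPKM (log2 change 4.60). Expansin-A8, a protein that loosens the wall, fell at Gohir.A13G006600 (A13, 755542 to 757405) from 60.3 ± 27.5 to 1.42 ± 1.82 FPKM (log2 change -4.82, SE 0.62, adjusted p = 0.00044). Phosphoinositide phospholipase C 2, Gohir.D06G169800 (D06, 60002057 to 60005978), rose from 36 ± 10 to 149.5 ± 44.2 FPKM (log2 change 2.02, SE 0.28, adjusted p = 0.000705). The inositol-3-phosphate synthase Gohir.A11G199700 (A11, 41816175 to 41818961), which makes inositol from glucose phosphate, fell from 3.75 ± 1.34 to 0.537 ± 0.217 FPKM (log2 change -1.60, SE 0.31, adjusted p = 0.00394). Of 61 phosphatidylinositol kinases, 1 rose and 15 fell (1 and 21 adjusted over the list alone). The median was -0.38 (camera adjusted p = 9.02e-05, adjusted p = 0.978 with an estimated correlation). Among 59 AP2/ERF and DREB factors, which act in stress responses, 17 rose and 2 fell (20 and 2 adjusted over the list alone). The median was 0.38 (camera adjusted p = 9.02e-05, adjusted p = 0.461 with an estimated correlation). Among 59 proline and soluble sugar genes 14 rose and 3 fell (15 and 4 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.000442, adjusted p = 0.94 with an estimated correlation). Among 85 gibberellin and cytokinin genes 16 rose and 6 fell (20 and 6 adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.013, adjusted p = 0.461 with an estimated correlation), a call lost on leaving out 1 library (adjusted p = 0.0511 without 30 min replicate 3).

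Ribosomal protein genes had more called members in leaf at 30 min, where of 870 genes 135 rose and 11 fell (126 and 9 adjusted over the list alone). The median was 0.35 (camera adjusted p = 2.72e-11, adjusted p = 0.978 with an estimated correlation). Of 259 heat shock proteins and factors, which fold other proteins or switch on their genes, 13 rose and 47 fell (15 and 51 adjusted over the list alone). The median was -0.27 (camera adjusted p = 0.0268, adjusted p = 0.978 with an estimated correlation), a call lost on leaving out 1 library (adjusted p = 0.0745 without 0 min replicate 3 and 0.123 without 30 min replicate 3). limma called 8247 of 46265 genes, 3852 higher and 4395 lower. Dividing each library by its own total gave 3563 higher and 4752 lower, but median-ratio scaling gave 4345 higher and 3785 lower, quantile scaling 4008 and 3835, and a filter at 5 FPKM 3539 and 3075. Without 0 min replicate 2 the count was 4574, without 30 min replicate 1 it was 4839 and without 30 min replicate 2 it was 5256.

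In leaf at 60 min a dehydrin, a protective protein of drying tissue, rose at Gohir.A01G107800 (A01, 20619138 to 20620273) from 20.3 ± 3.86 to 541 ± 256 FPKM (log2 change 4.54, SE 0.45, adjusted p = 0.000481). Heat shock cognate protein 80, Gohir.D13G133900 (D13, 47229546 to 47232641), fell from 146 ± 41.1 to 2.62 ± 1.18 FPKM (log2 change -5.36, SE 0.38, adjusted p = 0.000108). Of 259 heat shock proteins and factors, 3 rose and 59 fell (9 and 98 adjusted over the list alone). The median was -0.38 (camera adjusted p = 3.54e-13, adjusted p = 0.176 with an estimated correlation). Of 81 aquaporins, the water channels of cell membranes, 9 rose and 3 fell (19 and 4 adjusted over the list alone). The median was 0.42 (camera adjusted p = 9.91e-05, adjusted p = 0.978 with an estimated correlation). Among 168 WRKY factors 3 rose and 21 fell (7 and 36 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.00145, adjusted p = 0.978 with an estimated correlation). Calls lost on leaving out single libraries were those of calmodulin genes, where 1 rose and 8 fell of 42 (5 and 12 adjusted over the list alone, median -0.27, camera adjusted p = 0.0241, 0.123 without 0 min replicate 3, adjusted p = 0.978 with an estimated correlation), and C2H2 ZAT zinc fingers, where 0 rose and 1 fell of 29 (0 and 9 adjusted over the list alone, median -0.76, camera adjusted p = 0.000469, 0.103 without 0 min replicate 3, adjusted p = 0.978 with an estimated correlation). On the leaf axis 71.6% of aquaporins, 23.2% of WRKY factors, 26.2% of calmodulin genes and 10.3% of zinc fingers load on the positive side.

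The phosphatidylinositol kinases in leaf at 60 min had few called members, as of 61 genes 0 rose and 4 fell (0 and 4 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.000148, adjusted p = 0.978 with an estimated correlation). Of 85 gibberellin and cytokinin genes 8 rose and 0 fell (8 and 1 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.00639, adjusted p = 0.461 with an estimated correlation). Of 870 ribosomal protein genes 10 rose and 2 fell (0 and 0 adjusted over the list alone). The median was 0.26 (camera adjusted p = 1.99e-09, adjusted p = 0.978 with an estimated correlation). limma called 1825 genes in leaf at 60 min, 944 higher and 881 lower, fewer than at 30 min. Without 0 min replicate 1 there were 563 higher and 767 lower. The count was 626 without 0 min replicate 3, 960 without 0 min replicate 2, 682 and 665 without 60 min replicates 1 and 3, and 505 in a fit of the 6 libraries alone.

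Among leaf genes at 180 min, a gene described as a retinal pigment epithelial membrane protein, the domain of plant carotenoid cleavage dioxygenases that include an enzyme that makes abscisic acid, the hormone of water deficit, rose: Gohir.A13G152200 (A13, 98795895 to 98798145) from 0.323 ± 0.144 to 111 ± 16.9 FPKM (log2 change 6.40, SE 0.21, adjusted p = 1.86e-09). Abscisic acid 8'-hydroxylase 4, which inactivates the hormone, rose at Gohir.A03G189000 (A03, 111222659 to 111227213) from 0.393 ± 0.122 to 24.2 ± 11.1 FPKM (log2 change 4.08, SE 0.28, adjusted p = 1.05e-06), and the transcription factor ABSCISIC ACID-INSENSITIVE 5-like protein 6, Gohir.A12G023700 (A12, 3248526 to 3253398), from 18.2 ± 6.71 to 85.3 ± 9.6 FPKM (log2 change 2.22). Of 26 genes of abscisic acid synthesis and signalling, 12 rose and 0 fell (12 and 0 adjusted over the list alone). The median was 0.40 (camera adjusted p = 1.35e-06, adjusted p = 0.0855 with an estimated correlation). Among 200 type 2C protein phosphatases, a family with negative regulators of that hormone, 51 rose and 20 fell (53 and 21 adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.00728, adjusted p = 0.929 with an estimated correlation). Among 111 LEA proteins and dehydrins 29 rose and 4 fell (35 and 7 adjusted over the list alone). The median was 0.08 (camera adjusted p = 0.0128, adjusted p = 0.978 with an estimated correlation). The dehydrin Gohir.A01G107800 went from 20.3 ± 3.86 to 1277 ± 172 FPKM (log2 change 5.91). The LEA list lost its call on leaving out 1 library (adjusted p = 0.213 without 180 min replicate 3).

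Aquaporins were the leaf list with the largest median change at 180 min, as of 81 genes 40 rose and 4 fell (42 and 4 adjusted over the list alone). The median was 0.90 (camera adjusted p = 6.80e-13, adjusted p = 0.461 with an estimated correlation). The water channel Gohir.D04G113366 (D04, 42608883 to 42610420) rose from 20.6 ± 7.07 to 724 ± 263 FPKM (log2 change 5.04, SE 0.33, adjusted p = 7.18e-07). A WRKY gene was among the largest falls, Gohir.D07G035901 (D07, 3876361 to 3877865) from 521 ± 351 to 4.63 ± 6.17 FPKM (log2 change -6.96, SE 0.66, adjusted p = 1.49e-05). Of 168 WRKY factors, 18 rose and 39 fell (18 and 43 adjusted over the list alone). The median was -0.28 (camera adjusted p = 0.0268, adjusted p = 0.978 with an estimated correlation). Of 259 heat shock proteins and factors 21 rose and 99 fell (27 and 110 adjusted over the list alone). The median was -0.47 (camera adjusted p = 1.02e-06, adjusted p = 0.461 with an estimated correlation). WRKY factors lost the call on leaving out 1 library (adjusted p = 0.0914 without 0 min replicate 3), and so did proline and sugar genes as a list, where 19 rose and 7 fell of 59 (19 and 11 adjusted over the list alone, median 0.14, camera adjusted p = 0.0415, 0.293 without 180 min replicate 3, adjusted p = 0.978 with an estimated correlation).

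Phosphoinositide genes in leaf at 180 min changed in both directions. Of 26 diacylglycerol kinases, which turn diacylglycerol into phosphatidic acid, 1 rose and 11 fell (1 and 12 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0166, adjusted p = 0.978 with an estimated correlation), and 23.1% load on the positive side of the leaf axis. The kinase Gohir.D12G184100 (D12, 53311333 to 53319403) rose from 0.26 ± 0.0933 to 6.72 ± 0.289 FPKM (log2 change 2.62, SE 0.15, adjusted p = 2.11e-07), while Gohir.A08G235000 (A08, 125861374 to 125867441) fell from 12.3 ± 3.48 to 2.03 ± 0.103 FPKM (log2 change -2.11, SE 0.30, adjusted p = 0.000331). A phospholipase C gene, Gohir.A06G163500 (A06, 120879209 to 120883115), rose from 26.6 ± 2.2 to 143 ± 13.2 FPKM (log2 change 2.38, SE 0.24, adjusted p = 2.04e-05), and Phosphatidylinositol 4-phosphate 5-kinase 8, Gohir.D04G172200 (D04, 55671941 to 55677395), from 1.75 ± 0.393 to 6 ± 0.828 FPKM (log2 change 1.35). For phosphoinositide phospholipase C in leaf at 180 min 3 rose and 1 fell of 18 (3 and 1 adjusted over the list alone, camera adjusted p = 0.424). For inositol phosphate and phosphoinositide phosphatases 5 rose and 11 fell of 47 (5 and 11 adjusted over the list alone, camera adjusted p = 0.87). limma called 9019 of 46265 genes, 4574 higher and 4445 lower, and 13881 genes varied over the leaf time course in the F test. The count at 180 min was 5896 and 5790 without 180 min replicates 1 and 2.

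**Figure D2:**
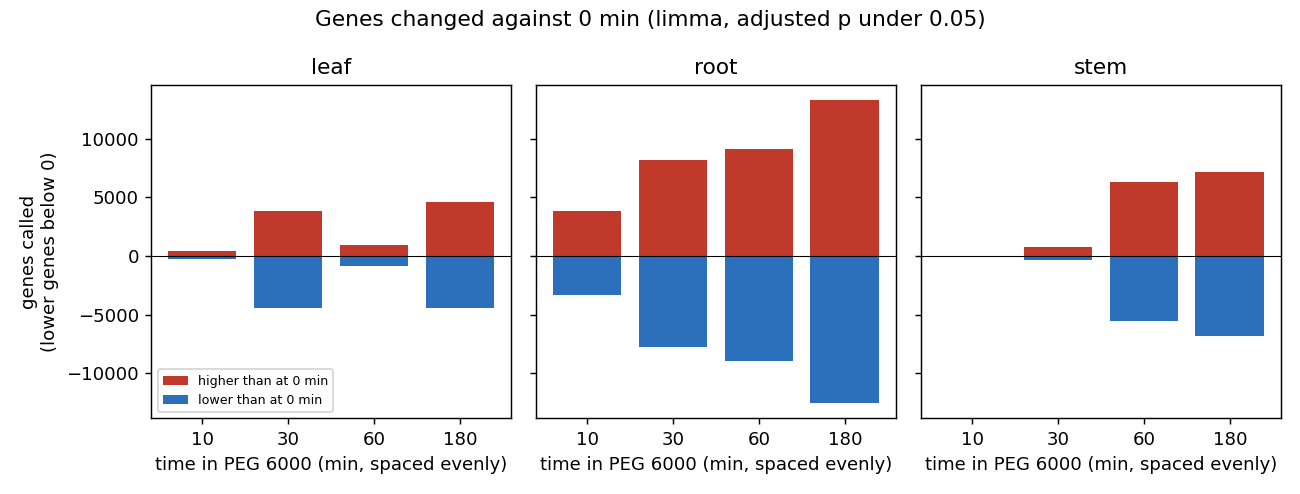
Genes called by limma at adjusted p under 0.05 against 0 min in each tissue (horizontal axis: time in PEG 6000 in minutes, spaced evenly; vertical axis: number of genes, with lower genes drawn below 0). Root bars reach 13311 higher and 12543 lower genes at 180 min, and stem has 1 called gene at 10 min.

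In root at 10 min transcription factor genes were among the strongest changes. An AP2 factor, Gohir.A02G137000 (A02, 100449828 to 100451448), rose from 1.92 ± 1.15 to 90.7 ± 10.3 FPKM (log2 change 5.04, SE 0.38, adjusted p = 4.93e-06). A CCCH zinc finger gene, Gohir.D06G168400 (D06, 59807805 to 59810761), fell from 185 ± 77.3 to 8.51 ± 1.32 FPKM (log2 change -4.21, SE 0.25, adjusted p = 2.42e-06). Of 50 C2H2 ZAT zinc fingers, 3 rose and 23 fell (4 and 25 adjusted over the list alone). The median was -0.68 (camera adjusted p = 9.15e-06, adjusted p = 0.684 with an estimated correlation). Of 27 diacylglycerol kinases, 10 rose and 0 fell (14 and 0 adjusted over the list alone). The median was 0.46 (camera adjusted p = 0.000579, adjusted p = 0.684 with an estimated correlation). Of 66 phosphatidylinositol kinases 3 rose and 7 fell (3 and 7 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.00784, adjusted p = 0.684 with an estimated correlation). Of 27 genes of inositol synthesis and inositol phosphate kinases, 8 rose and 0 fell (8 and 1 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.0114, adjusted p = 0.684 with an estimated correlation). Of 24 abscisic acid genes, 2 rose and 6 fell (3 and 10 adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.00854, adjusted p = 0.684 with an estimated correlation). The inositol list lost its call on leaving out 1 library (adjusted p = 0.0579 without 0 min replicate y).

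Jasmonate and defence genes also had root calls at 10 min. Of 129 genes of jasmonate synthesis and TIFY/JAZ repressors 32 rose and 7 fell (36 and 9 adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0114, adjusted p = 0.684 with an estimated correlation). Of 160 genes of wounding and defence 25 rose and 3 fell (32 and 5 adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.00833, adjusted p = 0.684 with an estimated correlation). Of 64 proline and soluble sugar genes 17 rose and 4 fell (20 and 4 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.011, adjusted p = 0.684 with an estimated correlation). Wounding and defence genes lost the call on leaving out 1 library (adjusted p = 0.0525 without 0 min replicate y). So did ribosomal genes, where 12 rose and 9 fell of 860 (1 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0124, 0.49 without 10 min replicate 3, adjusted p = 0.979 with an estimated correlation) and 85.9% load on the positive side of the root axis. The called members of the wounding and defence list were mainly wound-induced proteins and Bet v I proteins, not kinases. limma called 7093 of 46711 genes, 3810 higher and 3283 lower, or 3663 higher and 5130 lower with each library divided by its own total. The count was 4156 without 0 min library y and 4302 without 10 min replicate 2.

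At 30 min in root the diacylglycerol kinases Gohir.A07G069200 (A07, 9705832 to 9712367) and Gohir.D07G073600 (D07, 8580098 to 8586628) rose from 22.7 ± 5.73 to 181 ± 61.6 FPKM (log2 change 2.92, SE 0.29, adjusted p = 8.55e-06) and from 13.9 ± 2.4 to 101 ± 39 FPKM (log2 change 2.72, SE 0.25, adjusted p = 4.62e-06). The wound-induced gene Gohir.D02G183500 (D02, 66214299 to 66214559) rose from 1.56 ± 0.991 to 133 ± 58.6 FPKM (log2 change 5.70, SE 0.38, adjusted p = 5.20e-07). A class 3 lipase, Gohir.D10G045500 (D10, 4196288 to 4197874), which releases fatty acids, fell from 222 ± 74 to 4.97 ± 1.64 FPKM (log2 change -5.20, SE 0.30, adjusted p = 1.67e-07). Of 27 diacylglycerol kinases 13 rose and 0 fell (14 and 0 adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.00352, adjusted p = 0.684 with an estimated correlation). On the main axis of differences within root groups 22.2% of them, 31.8% of phosphatidylinositol kinases and 28.0% of C2H2 ZAT zinc fingers load on the positive side, and the 30 min libraries lay at 72.3, -23.6 and -48.7. Of 66 phosphatidylinositol kinases 6 rose and 17 fell (6 and 17 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.0201, adjusted p = 0.706 with an estimated correlation). Of 27 inositol synthesis and inositol phosphate kinase genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.0487, adjusted p = 0.684 with an estimated correlation). Of 24 abscisic acid genes 2 rose and 12 fell (2 and 12 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.0411, adjusted p = 0.684 with an estimated correlation). Of 50 C2H2 ZAT zinc fingers 7 rose and 24 fell (8 and 24 adjusted over the list alone). The median was -0.55 (camera adjusted p = 0.00351, adjusted p = 0.684 with an estimated correlation). Of 64 proline and soluble sugar genes 26 rose and 6 fell (27 and 7 adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.00854, adjusted p = 0.684 with an estimated correlation). Phosphatidylinositol kinases lost the call on leaving out 1 library (adjusted p = 0.0728 without 0 min replicate y and 0.0872 without 30 min replicate 1). So did inositol genes (adjusted p = 0.137 without 0 min replicate y, 0.0525 without 10 min replicate 1, 0.0579, 0.0537 and 0.0533 without 30 min replicates 1, 2 and 3 and 0.0556 without 180 min replicate 2). So did abscisic acid genes (adjusted p = 0.0666 without 0 min replicate y and 0.115 without 30 min replicate 1).

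Of 78 aquaporins in root at 30 min, 7 rose and 28 fell (8 and 29 adjusted over the list alone). The median was -0.69 (camera adjusted p = 0.00714, adjusted p = 0.816 with an estimated correlation). Of 131 measured photosynthesis genes, a list whose root calls include plastocyanin-like copper proteins, 6 rose and 28 fell (5 and 23 adjusted over the list alone). The median was -0.47 (camera adjusted p = 0.00714, adjusted p = 0.684 with an estimated correlation). limma called 15955 of 46711 genes, 8201 higher and 7754 lower. With each library divided by its own total the median of all genes was -0.18 and 6793 genes were higher and 11229 lower.

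At 60 min in root a wound-induced protein was among the largest rises. Gohir.D02G183500 went from 1.56 ± 0.991 to 665 ± 111 FPKM (log2 change 8.08, SE 0.38, adjusted p = 4.11e-08). Myo-inositol oxygenase, which oxidises inositol to glucuronate, rose at Gohir.D06G068200 (D06, 12627331 to 12629552) from 8.05 ± 1.68 to 84.6 ± 39.4 FPKM (log2 change 3.14, SE 0.33, adjusted p = 1.05e-05). Of 66 phosphatidylinositol kinases 6 rose and 26 fell (6 and 26 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.0114, adjusted p = 0.684 with an estimated correlation). Of 160 wounding and defence genes 54 rose and 32 fell (56 and 33 adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.0289, adjusted p = 0.684 with an estimated correlation). Of 131 photosynthesis genes 11 rose and 36 fell (10 and 36 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0114, adjusted p = 0.684 with an estimated correlation). The wounding and defence list lost its call on leaving out 1 library (adjusted p = 0.0837 without 0 min replicate y). limma called 18032 genes, 9105 higher and 8927 lower. With each library divided by its own total the median of all genes was -0.15 and 7317 genes were higher and 12071 lower.

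At 180 min in root the genes Gohir.A13G088800 (A13, 53201727 to 53205412) and Gohir.D13G086000 (D13, 18771171 to 18774676), described as phosphatidylinositol 3- and 4-kinases, rose from 9.42 ± 2.43 to 122 ± 44.3 FPKM (log2 change 3.52, SE 0.31, adjusted p = 7.29e-07) and from 6.99 ± 1.68 to 133 ± 61.8 FPKM (log2 change 3.96, SE 0.38, adjusted p = 1.37e-06). Of 66 phosphatidylinositol kinases, 9 rose and 34 fell (9 and 34 adjusted over the list alone). The median was -0.48 (camera adjusted p = 0.0125, adjusted p = 0.684 with an estimated correlation), a call lost on leaving out 1 library (adjusted p = 0.0653 without 180 min replicate 3). Inositol oxygenase 2, Gohir.A06G069600 (A06, 17121705 to 17123973), rose from 9.85 ± 4.1 to 206 ± 13.6 FPKM (log2 change 4.32, SE 0.45, adjusted p = 3.27e-06), and an inositol monophosphatase, Gohir.D06G128700 (D06, 43420596 to 43423186), from 0.508 ± 0.3 to 24.2 ± 6.25 FPKM (log2 change 4.05, SE 0.22, adjusted p = 1.23e-08). A phospholipase C gene fell, Gohir.D02G225200 (D02, 71149482 to 71150787) from 41.3 ± 5.42 to 5.05 ± 0.694 FPKM (log2 change -2.80, SE 0.20, adjusted p = 1.12e-07). For phosphoinositide phospholipase C in root at 180 min 5 rose and 9 fell of 20 (5 and 9 adjusted over the list alone, camera adjusted p = 0.301). For inositol phosphate and phosphoinositide phosphatases 15 rose and 11 fell of 47 (15 and 11 adjusted over the list alone, camera adjusted p = 0.711).

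Among root genes at 180 min, the small heat shock protein of 17.3 kDa, Gohir.A12G135400 (A12, 86773394 to 86774399) had 0 reads in the 3 root libraries at 0 min and stood at 42.0 ± 9.83 FPKM at 180 min (adjusted p = 6.31e-10), and the Hsp20 gene Gohir.A05G091700 (A05, 8769407 to 8770376) went from 0.0816 ± 0.141 to 44.5 ± 11.9 FPKM (log2 change 5.37, SE 0.19, adjusted p = 1.42e-09). Of 296 heat shock proteins and factors, 125 rose and 53 fell (130 and 54 adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.00351, adjusted p = 0.684 with an estimated correlation), but with each library divided by its own total their median turned to -0.14, while the median of all genes was -0.42. Proline dehydrogenase, which breaks down proline, rose at Gohir.A11G167900 (A11, 23077408 to 23080477) from 16.7 ± 4.66 to 489 ± 113 FPKM (log2 change 4.79, SE 0.23, adjusted p = 5.46e-09). Zeaxanthin epoxidase, of an early step of abscisic acid synthesis, fell at Gohir.D11G199300 (D11, 25104424 to 25108922) from 6.15 ± 0.155 to 0.472 ± 0.0282 FPKM (log2 change -2.28, SE 0.16, adjusted p = 8.57e-08).

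Of 129 jasmonate genes in root at 180 min 21 rose and 64 fell (21 and 64 adjusted over the list alone). The median was -0.57 (camera adjusted p = 0.00352, adjusted p = 0.684 with an estimated correlation). Allene oxide cyclase, an enzyme of jasmonate synthesis, fell at Gohir.A08G036300 (A08, 4638426 to 4639647) from 104 ± 36.9 to 4.96 ± 2.1 FPKM (log2 change -4.13). Of 27 genes of the circadian clock list, 2 of which are YUCCA10 genes of auxin synthesis, 19 rose and 3 fell (19 and 4 adjusted over the list alone). The median was 1.19 (camera adjusted p = 0.00442, adjusted p = 0.684 with an estimated correlation). Of 78 aquaporins, 8 rose and 34 fell (8 and 33 adjusted over the list alone). The median was -0.73 (camera adjusted p = 0.0368, adjusted p = 0.869 with an estimated correlation). The aquaporin list lost its call on leaving out 1 library (adjusted p = 0.0593 and 0.0579 without 0 min replicates 2 and y and 0.143 without 180 min replicate 1). On the root axis 79.5% of aquaporins and 22.2% of clock genes load on the positive side, and the 180 min root libraries lay at -73.0, -15.0 and 87.9. limma called 25854 of 46711 genes, 13311 higher and 12543 lower, and 31193 varied over the root time course in the F test. With each library divided by its own total, 7402 genes were higher and 20632 lower. The ratio of the deposited denominator to the total was 0.669 ± 0.0585 at 180 min against 1.01 ± 0.0313 at 0 min, and the 100 most counted genes took 14.9% ± 0.575 of reads against 8.38% ± 0.597.

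**Figure D3:**
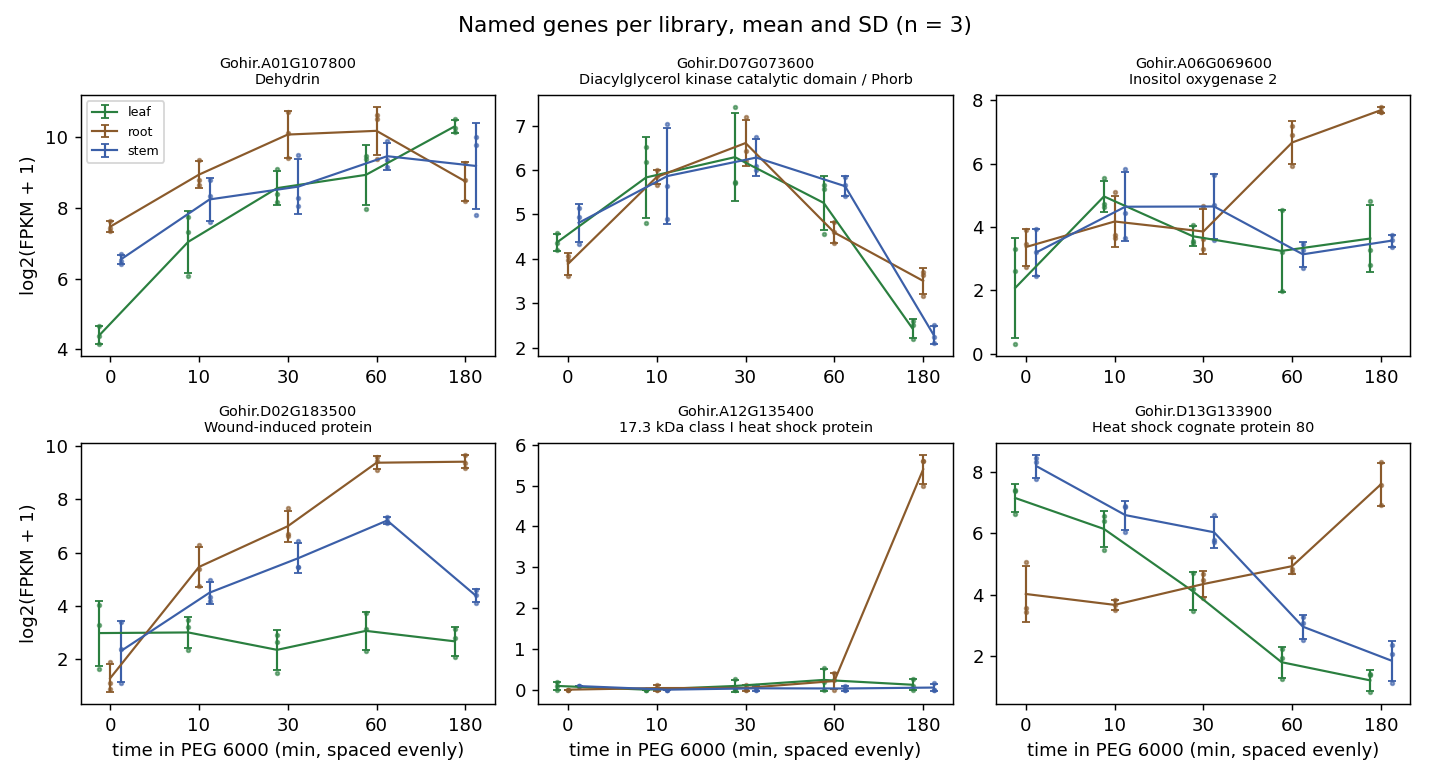
Levels of 6 genes as log2(FPKM + 1) (vertical axis) over time in PEG 6000 in minutes, spaced evenly (horizontal axis), with dots for single libraries and lines and bars for the mean and SD of 3 libraries per tissue. The small heat shock protein Gohir.A12G135400 stands at 42.0 ± 9.83 FPKM in root at 180 min and at 0.0900 ± 0.102 in leaf.

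In stem at 10 min 1 gene passed the test, Lysine-specific demethylase JMJ25, a histone demethylase. Gohir.D09G068400 (D09, 33158687 to 33164098) rose from 3.78 ± 0.564 to 11.9 ± 1.6 FPKM (log2 change 1.43, SE 0.16, adjusted p = 0.0288), a call lost on leaving out 0 min replicate 2 or 3 or 10 min replicate 1 or 2 (adjusted p of 0.0745, 0.08, 0.231 and 0.33). At an unadjusted p under 0.05 limma gave 4618 of 47698 genes. Lists with a camera call had no member called over all genes. Of 70 phosphatidylinositol kinases 0 rose and 0 fell (0 and 0 adjusted over the list alone). The median was -0.18 (camera adjusted p = 7.02e-06, adjusted p = 0.403 with an estimated correlation). Of 277 heat shock proteins and factors 0 rose and 0 fell (0 and 7 adjusted over the list alone). The median was -0.20 (camera adjusted p = 2.16e-06, adjusted p = 0.468 with an estimated correlation). Of 161 wounding and defence genes 0 rose and 0 fell (8 and 1 adjusted over the list alone). The median was 0.27 (camera adjusted p = 0.00188, adjusted p = 0.662 with an estimated correlation). Of 194 histone and cell cycle genes 0 rose and 0 fell (0 and 0 adjusted over the list alone). The median was -0.55 (camera adjusted p = 2.80e-08, adjusted p = 0.667 with an estimated correlation). Of 874 ribosomal genes 0 rose and 0 fell (0 and 0 adjusted over the list alone). The median was -0.19 (camera adjusted p = 5.88e-11, adjusted p = 0.662 with an estimated correlation). Calls lost on leaving out single libraries were those of cellulose and lignin genes, where 0 rose and 0 fell of 96 (0 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.0231, 0.13 without 10 min replicate 1, adjusted p = 0.631 with an estimated correlation), and proline and sugar genes, where 0 rose and 0 fell of 56 (0 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.0247, 0.274 without 10 min replicate 1, adjusted p = 0.777 with an estimated correlation). So was that of wounding and defence genes (adjusted p = 0.0847 without 10 min replicate 1). The main axis of differences within stem groups also had its sign set by the histone list. On its positive side load 78.9% of histone and cell cycle genes, 23.2% of proline and sugar genes and 23.4% of WRKY factors. The 0 min stem libraries lay at -88.8, 48.2 and 40.7.

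At 30 min in stem a wound-induced protein rose, Gohir.D02G183400 (D02, 66212629 to 66212889) from 8 ± 8.7 to 161 ± 40.1 FPKM (log2 change 4.64, SE 0.56, adjusted p = 0.00491). Flavonoid 3'-monooxygenase, of pigment synthesis, fell at Gohir.D11G140901 (D11, 14165119 to 14168043) from 61.8 ± 17.4 to 4.62 ± 1.39 FPKM (log2 change -3.47, SE 0.39, adjusted p = 0.00337). Of 161 wounding and defence genes 15 rose and 1 fell (27 and 2 adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.00022, adjusted p = 0.631 with an estimated correlation). Of 188 WRKY factors 13 rose and 3 fell (30 and 10 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.00258, adjusted p = 0.777 with an estimated correlation). Of 56 proline and soluble sugar genes 6 rose and 0 fell (10 and 2 adjusted over the list alone). The median was 0.48 (camera adjusted p = 0.000296, adjusted p = 0.662 with an estimated correlation). Of 20 phospholipase D genes, whose enzymes make phosphatidic acid, 1 rose and 0 fell (6 and 1 adjusted over the list alone). The median was 0.32 (camera adjusted p = 0.0357, adjusted p = 0.631 with an estimated correlation). Of 70 phosphatidylinositol kinases 0 rose and 3 fell (0 and 11 adjusted over the list alone). The median was -0.23 (camera adjusted p = 1.44e-05, adjusted p = 0.403 with an estimated correlation). Of 277 heat shock proteins and factors 1 rose and 12 fell (6 and 21 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.00828, adjusted p = 0.667 with an estimated correlation). Of 194 histone and cell cycle genes 1 rose and 0 fell (0 and 0 adjusted over the list alone). The median was -0.48 (camera adjusted p = 0.000409, adjusted p = 0.777 with an estimated correlation). Phospholipase D lost the call on leaving out 1 library (adjusted p = 0.119 without 0 min replicate 2, 0.0509 without 10 min replicate 1, 0.08 and 0.0801 without 30 min replicates 2 and 3 and 0.0636 and 0.05 without 180 min replicates 1 and 3). So did heat shock proteins (adjusted p = 0.162 without 0 min replicate 3). So did WRKY factors (adjusted p = 0.119 without 0 min replicate 2 and 0.0794 without 30 min replicate 3). So did ribosomal genes, where 1 rose and 2 fell of 874 (0 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.00338, 0.486 without 0 min replicate 2, adjusted p = 0.821 with an estimated correlation). So did histone genes (adjusted p = 0.0701 without 0 min replicate 2 and 0.0794 without 30 min replicate 3).

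limma called 1130 of 47698 stem genes at 30 min, 768 higher and 362 lower, or 634 higher and 464 lower with each library divided by its own total. The count was 662 and 93 without 0 min replicates 2 and 3, and 176, 619 and 247 without 30 min replicates 1, 2 and 3. A fit of the 6 libraries alone gave 4.

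At 60 min in stem a glutathione S-transferase, a detoxifying enzyme, rose at Gohir.A09G161200 (A09, 76234070 to 76235396) from 0.919 ± 0.912 to 252 ± 132 FPKM (log2 change 7.01, SE 0.67, adjusted p = 0.000112), and a globin, an oxygen-binding protein, at Gohir.D04G174100 (D04, 55916572 to 55918093) from 0.884 ± 1.11 to 105 ± 35.3 FPKM (log2 change 5.93, SE 0.56, adjusted p = 0.000104). An AP2 factor, Gohir.A12G024200 (A12, 3353934 to 3354811), fell from 139 ± 101 to 2.11 ± 0.571 FPKM (log2 change -5.25, SE 0.58, adjusted p = 0.000218), and Heat shock cognate protein 80, Gohir.D13G133900, from 299 ± 71.9 to 6.95 ± 2.04 FPKM (log2 change -5.24, SE 0.37, adjusted p = 3.98e-05). Of 277 heat shock proteins and factors 17 rose and 85 fell (18 and 95 adjusted over the list alone). The median was -0.44 (camera adjusted p = 2.73e-06, adjusted p = 0.468 with an estimated correlation). Of 70 phosphatidylinositol kinases 3 rose and 20 fell (6 and 26 adjusted over the list alone). The median was -0.32 (camera adjusted p = 0.00355, adjusted p = 0.502 with an estimated correlation). Of 188 WRKY factors 48 rose and 14 fell (56 and 16 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.01, adjusted p = 0.777 with an estimated correlation). Of 161 wounding and defence genes 44 rose and 11 fell (48 and 11 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.000809, adjusted p = 0.631 with an estimated correlation). Of 194 histone and cell cycle genes 7 rose and 23 fell (0 and 6 adjusted over the list alone). The median was -0.79 (camera adjusted p = 0.000147, adjusted p = 0.777 with an estimated correlation). Of 224 photosynthesis genes 5 rose and 37 fell (2 and 22 adjusted over the list alone). The median was -0.46 (camera adjusted p = 4.89e-05, adjusted p = 0.667 with an estimated correlation). WRKY factors lost their call on leaving out 1 library (adjusted p = 0.119 without 0 min replicate 2). limma called 11876 of 47698 genes, 6352 higher and 5524 lower, or 7237 higher and 4310 lower with each library divided by its own total. The count was 7375 and 6172 without 0 min replicates 2 and 3, and 7358 and 5253 without 60 min replicates 2 and 3.

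At 180 min in stem diacylglycerol kinase and phosphatidylinositol kinase genes with the smallest p were lower. Gohir.A07G069200 fell from 73.1 ± 18 to 4.38 ± 0.296 FPKM (log2 change -3.75, SE 0.39, adjusted p = 5.20e-05) and Gohir.D07G073600 from 27.8 ± 7.8 to 3.89 ± 0.709 FPKM (log2 change -2.53). The gene Gohir.A10G050500 (A10, 5215420 to 5222795), with a phosphatidylinositol-4-phosphate 5-kinase and a chaperonin domain, fell from 8.75 ± 3.71 to 0.228 ± 0.0903 FPKM (log2 change -2.91, SE 0.35, adjusted p = 0.000115). Inositol-tetrakisphosphate 1-kinase 3, Gohir.D05G217400 (D05, 19458132 to 19462848), fell from 18.9 ± 3.79 to 4.67 ± 0.548 FPKM (log2 change -1.80, SE 0.22, adjusted p = 0.000131), and an inositol monophosphatase, Gohir.A10G156800 (A10, 92396383 to 92405519), from 13.9 ± 3.5 to 3 ± 1.38 FPKM (log2 change -1.93). Of 27 genes of inositol synthesis and inositol phosphate kinases, 1 rose and 7 fell (1 and 7 adjusted over the list alone). The median was -0.64 (camera adjusted p = 0.0367, adjusted p = 0.631 with an estimated correlation), a call lost on leaving out 1 library (adjusted p = 0.0662 and 0.0678 without 0 min replicates 1 and 2 and 0.0539 and 0.0557 without 180 min replicates 1 and 3). For phosphoinositide phospholipase C in stem at 180 min 0 rose and 2 fell of 19 (0 and 1 adjusted over the list alone, camera adjusted p = 0.557). For inositol phosphate and phosphoinositide phosphatases 5 rose and 13 fell of 49 (5 and 14 adjusted over the list alone, camera adjusted p = 0.413).

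Of 78 aquaporins in stem at 180 min, 32 rose and 2 fell (32 and 3 adjusted over the list alone). The median was 0.77 (camera adjusted p = 0.00042, adjusted p = 0.655 with an estimated correlation). The water channel Gohir.A10G233200 (A10, 116892425 to 116894160) went from 2.87 ± 1.24 to 76.9 ± 8.88 FPKM (log2 change 4.37, SE 0.44, adjusted p = 3.81e-05). Of 277 heat shock proteins and factors 24 rose and 91 fell (28 and 100 adjusted over the list alone). The median was -0.36 (camera adjusted p = 5.86e-05, adjusted p = 0.502 with an estimated correlation). Of 42 calmodulin genes 3 rose and 14 fell (3 and 15 adjusted over the list alone). The median was -0.39 (camera adjusted p = 0.00234, adjusted p = 0.403 with an estimated correlation). Of 194 histone and cell cycle genes 13 rose and 36 fell (13 and 27 adjusted over the list alone). The median was -0.75 (camera adjusted p = 0.000215, adjusted p = 0.777 with an estimated correlation). Cyclin-D2-2, a driver of the cell cycle, fell at Gohir.A13G047200 (A13, 6151981 to 6154297) from 5.96 ± 1.97 to 0.64 ± 0.311 FPKM (log2 change -2.06, SE 0.23, adjusted p = 6.19e-05). Cellulose synthase A catalytic subunit 2, Gohir.D03G048100 (D03, 7230734 to 7237378), which makes wall cellulose, fell from 73.9 ± 6.12 to 9.01 ± 2.7 FPKM (log2 change -2.94, SE 0.24, adjusted p = 1.10e-05). Of 139 jasmonate and TIFY/JAZ genes 9 rose and 33 fell (9 and 34 adjusted over the list alone). The median was -0.27 (camera adjusted p = 0.0244, adjusted p = 0.667 with an estimated correlation). Of 618 MYB factors 142 rose and 57 fell (147 and 59 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0129, adjusted p = 0.468 with an estimated correlation). MYB factors lost the call on leaving out 1 library (adjusted p = 0.0557 without 180 min replicate 3). So did C2H2 ZAT zinc fingers, where 3 rose and 11 fell of 36 (3 and 13 adjusted over the list alone, median -0.54, camera adjusted p = 0.0269, 0.134 without 180 min replicate 1, adjusted p = 0.777 with an estimated correlation). So did jasmonate genes (adjusted p = 0.0979 without 0 min replicate 1 and 0.0636 without 180 min replicate 1).

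Single stem genes with large changes at 180 min were Probable WRKY transcription factor 70, Gohir.A05G404200 (A05, 109632849 to 109634207), which fell from 136 ± 83.6 to 0.734 ± 0.608 FPKM (log2 change -6.18, SE 0.40, adjusted p = 4.78e-06), and the AP2 factor Gohir.A11G009200 (A11, 867757 to 868425), which fell from 286 ± 79.5 to 1.73 ± 1.03 FPKM (log2 change -6.75, SE 0.47, adjusted p = 6.31e-06). Abscisic acid 8'-hydroxylase 4 rose in stem from 0.186 ± 0.185 to 11.6 ± 8.01 FPKM (log2 change 3.20, SE 0.37, adjusted p = 9.28e-05). limma called 13983 of 47698 genes, 7164 higher and 6819 lower, or 8867 higher and 5709 lower with each library divided by its own total. In the F test 16416 varied over the stem time course. The count at 180 min was 8853 without 180 min replicate 2.

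**Figure D4:**
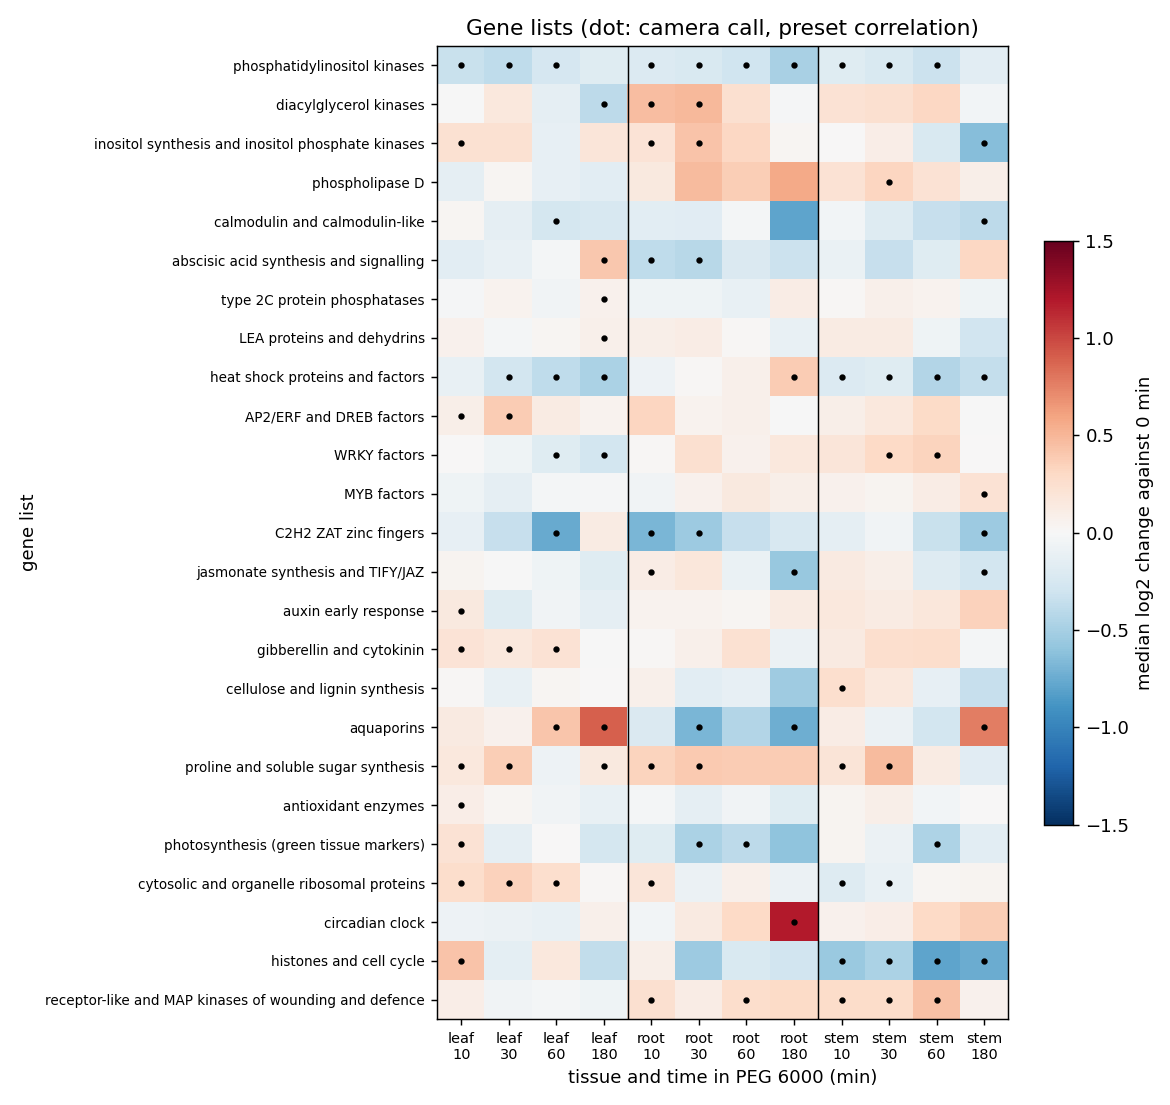
Median log2 change against 0 min (colour, from -1.5 to 1.5) of the gene lists with a camera call, by tissue and time in minutes (horizontal axis) and list (vertical axis), with a dot where the call with a preset correlation passed. Phosphatidylinositol kinases have a dot and a median below 0 in 10 of 12 comparisons, and aquaporins have medians of 0.90 in leaf, -0.73 in root and 0.77 in stem at 180 min.

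The lists with 0 camera calls in any tissue are given at 180 min in root, where most genes were called. For calcium-dependent and CBL-interacting protein kinases 14 rose and 9 fell of 33 (14 and 9 adjusted over the list alone, camera adjusted p = 0.46). For NAC factors 12 rose and 10 fell of 43 (12 and 10 adjusted over the list alone, camera adjusted p = 0.804). For ethylene synthesis 5 rose and 2 fell of 17 (4 and 2 adjusted over the list alone, camera adjusted p = 0.909). For xyloglucan hydrolases and expansins 6 rose and 5 fell of 18 (6 and 5 adjusted over the list alone, camera adjusted p = 0.909). For low-oxygen response genes 83 rose and 44 fell of 184 (84 and 44 adjusted over the list alone, camera adjusted p = 0.0574). For mineral nutrient transporters 27 rose and 48 fell of 123 (27 and 51 adjusted over the list alone, camera adjusted p = 0.116).

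Tests of the difference between tissues asked where responses diverged. Small heat shock proteins were among the genes with the smallest interaction p between root and the other tissues. Gohir.D07G026300 (D07, 2859721 to 2860197), a 16.9 kDa chaperone, had 0 reads in leaf, in stem and in root at 0 min. It stood at 18 ± 4.84 FPKM in root at 180 min (leaf minus root -4.21). A glutathione S-transferase, Gohir.A13G152401 (A13, 98876249 to 98877000), stood at 37.1 ± 9.28 FPKM in root at 180 min, against 0 ± 0 in leaf and 0.166 ± 0.155 in stem (root minus stem 4.82). Other groups of these genes lay at or near 0, so the pooled SE understates the root spread and p is left out. The heat shock factor Gohir.A05G030700 (A05, 3110903 to 3112796) reached 6.47 ± 0.933 FPKM in leaf and 0.0952 ± 0.0357 in stem at 180 min (leaf minus stem 2.99). A patatin-like phospholipase, Gohir.A06G016650 (A06, 1633045 to 1637728), went from 36 ± 14.8 to 0.897 ± 0.387 FPKM in leaf and from 0.127 ± 0.111 to 16.5 ± 14.2 in stem (leaf minus stem -7.91). The other groups of the heat shock factor and the root groups of the phospholipase also lay at or near 0, so p is left out here too. Of 54622 genes tested, the time course differed for 23386 between leaf and root, 8345 between leaf and stem and 20176 between root and stem. Without the libraries numbered 2 these counts were 10295, 1076 and 8303, and without those numbered 1 they were 13753, 3481 and 11801.

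Aquaporins differed between root and the other tissues at 180 min with the preset correlation, where root libraries lay far apart on an axis that holds 79.5% of root aquaporins on its positive side. Their median difference was 1.46 for leaf minus root (camera adjusted p = 3.40e-10, adjusted p = 0.476 with an estimated correlation) and -1.33 for root minus stem (camera adjusted p = 4.66e-09, adjusted p = 0.510 with an estimated correlation). Heat shock proteins and factors differed by -0.57 for leaf minus root (camera adjusted p = 1.04e-09, adjusted p = 0.139 with an estimated correlation). Abscisic acid genes differed by 0.66 for leaf minus root at 180 min (camera adjusted p = 0.000823, adjusted p = 0.453 with an estimated correlation). The phosphatidylinositol kinases showed no call between tissues at any time, where the smallest camera adjusted p was 0.134, for root minus stem at 180 min. Among 65 list differences called with the preset correlation, 1 passed with an estimated correlation, that of the mineral nutrient transporters for root minus stem at 180 min (median -0.33, adjusted p = 0.0161).

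Called genes overlapped between tissues. At 180 min 4157 genes were higher in both root and stem where 1859 would be expected of independent lists, 3597 were lower in both (1646 expected) and 991 went opposite ways (3499 expected), over 41972 genes tested in both. Leaf and stem shared 1975 higher (668 expected) and 1945 lower genes (603 expected), and leaf and root 1986 higher (1138 expected) and 1832 lower genes (1025 expected), with 331 (1269 expected) and 1375 (2160 expected) going opposite ways.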

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

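Tests chosen only after the result was seen are the shuffles of tissue labels and the alternatives run on gene list differences between tissues. Each result below drew a closer look because the response differed between tissues in a test of the difference itself. The time course differed for 23386 genes between leaf and root, 8345 between leaf and stem and 20176 between root and stem. Tissue labels were shuffled within each time after removing tissue means, which keeps the shared response. For each pair 1 of 100 draws, the real one, called as many genes (highest others 16287, 2472 and 5517). Chance can be excluded only if libraries are independent.

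Small heat shock proteins and a detoxifying enzyme set root apart at 180 min. For leaf minus root the difference was -5.12 for the glutathione S-transferase Gohir.A13G152401, -4.21 for Gohir.D07G026300 and -5.37 for Gohir.A12G135400. For root minus stem it was 4.82, 4.21 and 5.44 for the same genes. The change in leaf minus the change in stem was 3.19 for Gohir.D12G259100, a CAP160 repeat protein, 2.99 for the heat shock factor Gohir.A05G030700 and -7.91 for the patatin-like phospholipase Gohir.A06G016650.

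All lists here had opposite calls in 2 tissues at the times given. They include heat shock proteins at 180 min (median difference -0.57 for leaf minus root, 0.72 for root minus stem) and aquaporins at 180 min (1.46 and -1.33). WRKY factors differed by -0.55 for leaf minus stem at 60 min. Ribosomal proteins differed by 0.44 and 0.46 for leaf minus stem at 10 and 30 min and by 0.38 for root minus stem at 10 min, and histone genes by 0.87 for leaf minus stem at 10 min. At 10 min 0 ribosomal genes were called in leaf or stem. Of ribosomal genes 73.6% in leaf, 85.9% in root but 51.5% in stem load on the positive side of the axis below. For histone genes, which set the sign of the axis, it was 83.9% in leaf and 78.9% in stem. With an estimated correlation the adjusted p of these list differences ran from 0.0543 (heat shock, root minus stem) to 0.816 (ribosomal, root minus stem).

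Other splits of the libraries were counted for each result. Shuffled labels gave as many genes as the F tests in 1 of 100 splits for leaf (13881 real, highest other 1392), root (31193, 13094) and stem (16416, 3881). A random split is thus an unlikely source of these counts, again only if libraries are independent. For 2 groups of 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes in leaf at 10, 30, 60 and 180 min (698, 8247, 1825 and 9019, highest others 97, 1, 0 and 0) and in root (7093, 15955, 18032 and 25854, highest others 3, 1, 0 and 1). It was so too in stem at 30, 60 and 180 min (1130, 11876 and 13983, highest others 0, 0 and 23). At 0 min the counts were 25786, 16748 and 22932 for leaf and root, leaf and stem, and root and stem (highest others 22, 334 and 409). In stem at 10 min 2 of the 10 splits gave as many as the real count of 1. The split of 0 min replicate 1 with 10 min replicates 1 and 2 against the rest gave 319, which points to a structure of the samples.

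Libraries of 1 group lay apart along the plotted axis. Sequencing depth is argued against, since the position had a Spearman rho of -0.065 with total reads (permutation p = 0.699) and a Pearson correlation of -0.0307 (p = 0.834, and -0.124 without the 2 farthest) over 45 libraries. Gene length is argued against too, as the largest rho between a gene's loading and its length was -0.0529. Time of harvest, position or handling of single plants were not recorded and stay open. No biological explanation was tested.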

How the results depend on the processing

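Alternatives on recovered reads, library totals, lists without single libraries and list differences between tissues were chosen after seeing the data. Of 184 named gene results none reversed: 1898 comparisons under other settings kept the call and 9 lost it, and leaving out 1 library, or all of 1 replicate number for tissue comparisons, kept 948 and lost 24. Of the 86 list calls, 627 comparisons kept the call and 172 lost it, and leaving out 1 library kept 1208 and lost 82. Gene counts stayed within 1.5 times in 259 comparisons, rose in 19 and fell in 25.

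Library weights raised counts to 17060, 10641 and 15683 in leaf at 30, 60 and 180 min, 12035 and 26500 in root at 10 and 30 min, and 1290, 6986 and 22089 in stem at 10, 30 and 60 min. They gave 25836 and 29109 genes for the F tests in leaf and stem, and 41415, 30672 and 44979 for the differences between leaf and root, leaf and stem, and root and stem. The weights are not trusted, since their fit gave convergence warnings and root 180 min replicate 2 had a weight of 97.9.

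A log2 change of at least 1 left 3789 and 4821 genes in leaf at 30 and 180 min, 3751, 7911, 8637 and 14780 in root, and 6111 and 7911 in stem at 60 and 180 min, by construction fewer. Fits of the 6 libraries alone gave 2 and 505 in leaf at 10 and 60 min and 0, 4 and 6468 in stem at 10, 30 and 180 min, with fewer residual degrees of freedom. Fits of all 45 gave 1317 and 2916 in leaf at 10 and 60 min and 503 and 3815 in stem at 10 and 30 min. In stem a pseudocount of 0.1 gave 2 genes at 10 min, no filter 751 at 30 min and voom 598 at 30 min, where the cause was not tested.

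With the replicate block counts were 385 and 1199 in leaf at 10 and 60 min and 0 and 502 in stem at 10 and 30 min. JMJ25 lost its call (adjusted p = 0.0868). Same-numbered libraries correlated after removing group means with a median of -0.0725 in leaf, 0.0614 in root and -0.0917 in stem. Pairing between tissues was not tested.

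The gene list tests depend most on the correlation. With an estimated correlation 0 of the 86 calls passed, and 1 of 65 differences between tissues. At an unadjusted p under 0.05 camera with an estimated correlation gave 27 of 396 list tests, 17 of them among the 86. The test fry called 17 in leaf, 63 in root and 28 in stem, and kept 51 of the 86 calls and lost 35.

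Leaving out 1 library gave 159 to 741, 4574 to 6980, 626 to 1904 and 5790 to 7173 genes in leaf at 10, 30, 60 and 180 min and 10046 to 15014 in its F test. In root these were 4156 to 5983, 12032 to 16440, 13893 to 15829, 21836 to 27303 and 27441 to 32939, and in stem 0 to 40, 93 to 1006, 5253 to 13264, 8853 to 16996 and 11432 to 18274. Without all libraries of 1 replicate number, response differences ran from 10295 to 20710, 1076 to 7076 and 8303 to 14891, and differences at 0 min from 17582 to 23771, 9889 to 13977 and 14032 to 20363. List calls ran from 27 to 34 in leaf, 17 to 32 in root and 25 to 36 in stem. A group left with 2 libraries keeps the spread of the whole fit. Fewer libraries leave less power, and the cause was not tested further. Depth limits genes of low level, since genes that reached 1 FPKM in fewer than 3 libraries of a fit were not tested.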

Other observations

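Families in this part were picked from Pfam counts after the data were seen, and so were the fermentation genes, their tests of scaling and the test of time of day. Wound-induced proteins rose in 22 of 22 members in root at 60 min (4.29 expected) and 20 of 21 in stem (2.80 expected). Of acyl-CoA dehydrogenases, which break down fatty and amino acids, those with the C-terminal domain rose in 16 of 16 members in root at 180 min (4.56 expected), 16 of 16 in stem (2.40 expected) and 12 of 16 in leaf (1.58 expected). Those with the middle domain rose in 18 of 21 in root and 15 of 21 in stem. Atg8 proteins, which mark the membranes of autophagy, rose in 18 of 21 in root at 180 min (5.98 expected) and 14 of 22 in stem (3.30 expected). MCM2/3/5 proteins, the helicase of DNA replication, fell in 16 of 18 members in stem at 60 min (2.08 expected).

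In leaf at 10 min 14 of 53 glycosyl hydrolases of family 16, which remodel wall xyloglucan, rose (0.469 expected). Of Hsp20 proteins at 180 min 46 of 64 rose in root (18.2 expected) and 24 of 41 fell in leaf (3.94 expected). A gene can pass the filter by its rise alone, as Gohir.A12G135400 in root, so members differ here and in heat shock lists. The difference was not tested here, and for all heat shock genes had adjusted p = 0.139 with an estimated correlation. NB-ARC resistance proteins fell in 154 of 340 members in root at 180 min (91.3 expected).

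Of 10 genes picked by words for fermentation and globins after their values were seen, 2 of which are described as Cinnamyl alcohol dehydrogenase 1, 4 rose and 3 fell in root at 180 min (camera p = 0.488, and 0.585 with an estimated correlation). At 180 min globin Gohir.A04G129000 went from 9.81 to 2101 FPKM (log2 change 8.09, adjusted p = 4.03e-07) and Pyruvate decarboxylase 1, Gohir.D05G159000, which starts ethanol fermentation, from 2.30 to 530.5 FPKM (7.26, adjusted p = 1.08e-07). In stem Gohir.D05G159000 rose by 4.73 at 60 min and by 1.16 at 180 min (adjusted p = 0.1003, not called). Other members fell in root, as globin Gohir.D01G118300 by -3.57 at 180 min (adjusted p = 0.000449) and Alcohol dehydrogenase 1, Gohir.D11G060400, by -0.97 at 60 min (adjusted p = 0.0116).

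The scaling between libraries was weighed first. With each library divided by its own total the median of these 10 genes in root at 180 min was -0.17, but members went both ways, so this decides nothing. The lowest of the 4 risers still changed by 6.67, which argues against scaling for them. Low oxygen at the roots, a biological explanation, stays open: 50 other low-oxygen genes had a median of 0.70 with 28 up and 10 down (camera p = 0.000586), but p = 0.1 with an estimated correlation, and the median was 0.20 with library totals. Oxygen was not measured, so low oxygen and PEG cannot be told apart.

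Clock genes could change with the time of day, since no untreated plants were sampled later. Counting each gene of the clock list once per pair of tissues in which it was called at 180 min, 80% of cases (16 of 20, 1 of the 16 a YUCCA10 gene) changed the same way. Over all genes it was 85.2% (15492 of 18189), so the test does not set time of day apart from PEG.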
